A study of Escherichia coli with 2 samples.

How the data were processed

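Total RNA of biofilm cells was labelled with biotin and hybridised to the Affymetrix E. coli Antisense array, 1 array for BW25113 wild type and 1 for the ycfR deletion mutant, after 15 h on glass wool. The groups came from the sample titles. The deposited values are signal intensities per probe set on a linear scale, made with MAS5 per the submitters' processing notes, whose version is not given in the sources used here. MAS5 combines the perfect-match and mismatch probes of a probe set into 1 signal. In both deposited columns the mean signal after leaving out the lowest and the highest 2% of probe sets was 500.1, so each array had been scaled to a common target. Signals ran from 0 to 6937 in the wild type and from 0.1 to 20709 in the deletion array. Detection calls and probe-level intensities were not used here, so whether a signal was above background was judged from signal levels alone. With 1 array per group the number of arrays limits the precision, and neither an error nor a p-value can be given.

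Of the 7312 probe sets, 4345 carried the b number of a K-12 gene in their identifier, 2886 stood for intergenic regions, 22 were manufacturer controls and 59 were phage or plasmid probe sets. Of the 4345 b numbers, 4183 matched a gene of the RefSeq table for assembly ASM584v2, which gave the current symbol, and 162 did not and kept the name of the array. Where both the table and the platform annotation gave a gene number, 4142 of 4151 matched. The platform annotation listed 1 gene symbol for 3804 probe sets, several for 594 and none for 2914. Each K-12 gene had 1 probe set, and 126 gene probe sets are marked by the manufacturer as shared between near-identical sequences. The genome build behind the array design is not given in the sources used here, so no coordinates are printed.

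The log2 ratio of a gene was the log2 signal of the deletion array minus that of the wild-type array, as deposited, without a pseudocount. A gene passed the filter and is called measurable when the brighter of its signals was at or above the array's median over K-12 genes (435.1 in the wild type, 399.4 in the deletion array) and both were at or above their array's 25th percentile (314.6 and 279.2). When the dimmer signal was below that percentile, the brighter signal was divided by the percentile of the dimmer array and written as "at least N-fold", which applied to 116 genes. The fixed size rule was a ratio of at least 2-fold. For 33 gene lists, written before the data were examined, the median log2 ratio over members whose mean log2 signal was at or above the 25th percentile was placed among 10000 random lists of the same size, matched on mean signal in 10 bins. Because this filter differs from that of the 2-fold count, a median can cover more members than the count. Lists outside the 5th to 95th percentile are said to stand apart, as a description of these arrays. Lists with fewer than 4 such members, curli and the genes deleted in the parent strain, got values only.

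Named genes followed a rule written before the data were examined. It took ycfR and its neighbours, and the 12 measurable genes with the largest log2 ratio in each direction. It also took up to 3 genes with the largest bounds in each direction. From each list it took up to 3 measurable members with the largest absolute log2 ratio (4 for lists that stood apart). List members with a bound only could therefore be left out. With the 6 genes deleted in the parent strain this gave 133 genes in all. The genes gadX, gadW, gadE, hdeA, hdeB, slp, dps, aceA, aceB, acnA, gltA, gatY, cyoE and cspB were named outside that rule, after their values were seen. So were the mal, nuo and cyo groups and each gene in the closing section that the rule did not give. The correlation of neighbouring genes was planned over adjacent genes of the same strand. The gene table used gives no strand, so adjacent protein-coding genes were instead divided at a gap of 50 bases.

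The steps were tested on simulated data with 4345 genes, 200 of them changed, and noise of 0.315 (log2 SD per array). The noise was the same for every gene, without a trend with brightness, a floor, shared operons or variation between cultures. Changed genes were drawn from the brighter genes only. The rates that follow hold for that setting and are not error rates of the real arrays. Of 100 genes changed 3-fold, 72 were found and 17 had bounds only. Of 100 changed 6-fold, all 67 that passed the filter were found and 33 had bounds only. Of 2266 unchanged genes that passed the filter, 2.12% were called. Of 200 simulated lists without change 10.0% lay outside the 5th to 95th percentile, and 98.5% of lists of 15 genes shifted by 0.5 were found.

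Alternatives planned before the data were examined were median centring, quantile normalization, a lowess of the log2 ratio on mean log2 signal (span 0.3), a pseudocount of the 25th percentile, no filter, a filter at the 75th percentile, a filter at the highest signal of the genes deleted in the parent strain, thresholds of 1.5-fold and 3-fold, random lists without matching and matching in 20 bins. Chosen after seeing the data were a scaling on 12 probe sets of added bacterial control transcripts (Dap, Lys, Phe and Thr), the subtraction of each array's 10th percentile as a floor, and a count without shared probe sets and without ribosomal and transfer RNA. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.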

Results

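Transcript levels were measured in biofilm cells of Escherichia coli K-12 strain BW25113 and of its ycfR deletion mutant, both grown on glass wool for 15 h in LB medium labelled "LB glu". BW25113 is the laboratory strain from which many single-gene deletion mutants were made. The gene ycfR, now named bhsA, encodes a small outer membrane protein that is known for its link to stress resistance and biofilm formation. The comparison asks how the transcripts of biofilm cells differ when ycfR is missing. There were 2 Affymetrix arrays, 1 for the wild type and 1 for the deletion mutant. No value below therefore has a replicate check, an error or a p-value, and every difference is a difference between these 2 arrays. Each array carried 7312 probe sets, of which 4345 stood for K-12 genes, 1 probe set per gene. The median signal over K-12 genes was 435.1 in the wild type and 399.4 in the deletion array. The brightest probe set, for ribosomal RNA on both arrays, reached 6937 in the wild type and 20709 in the deletion array. Compression of the wild-type array at the bright end and higher transcript levels in the deletion sample cannot be told apart here. Whether the wild-type array was saturated there was not tested. This limits what the ratios of genes as bright as dps, osmY and hdeA can mean. It is stated where a lowess on mean signal ends a 2-fold difference of a named gene. Across genes, the log2 signals of the 2 arrays had a Pearson correlation of 0.874, and genes are not independent replicates.

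**Figure D1:**
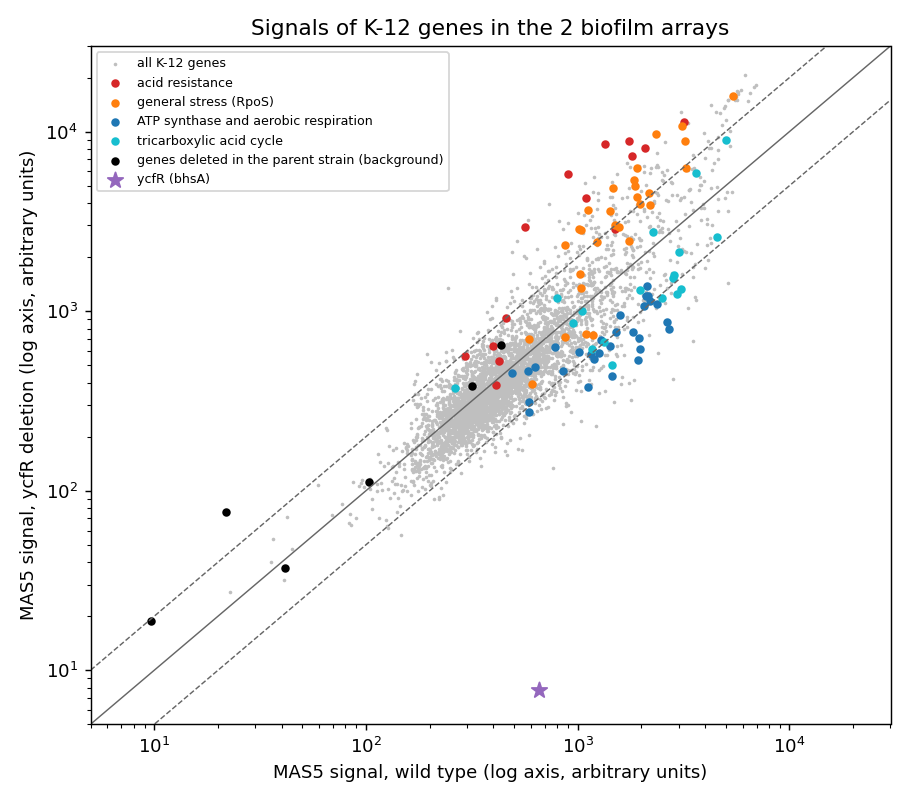
Each point is a K-12 gene, with its signal in the wild-type array on the horizontal axis and in the ycfR deletion array on the vertical axis, both on log scales in arbitrary intensity units. The gene ycfR has a signal of 653.4 in the wild type and 7.8 in the deletion array, and the brightest genes bend above the diagonal.

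The deleted gene was read first, because it checks the labels. The ycfR probe set had a signal of 653.4 in the wild type and 7.8 in the deletion array, a log2 ratio of -6.39. The latter signal lies inside the range of probe sets for phage and plasmid sequences on the same array, which ran from 0.6 to 161.3 with a median of 13.7. Because the deletion signal was below the 25th percentile of its array, the difference is given as a bound of at least 2.34-fold. The genes next to ycfR showed no comparable difference. The signal of comR (ycfQ), the gene of a repressor of ycfR, was 880.1 in the wild type and 736.4 in the deletion array. The signal of ldtC (ycfS), an L,D-transpeptidase gene, was 618.8 and 605.4. The log2 ratios of ycfJ, ycfP and mfd were 0.23, 0.21 and -0.35. The genes ndh and lolC were too dim for the filter, with log2 ratios of -0.33 and -0.98. As a further background, the parent strain lacks the arabinose genes araA and araB and the rhamnose genes rhaA and rhaB, whose signals were 9.6, 41.5, 21.9 and 103.8 in the wild type and 18.7, 36.9, 75.6 and 111.2 in the deletion array. Probe sets for araD and rhaD, from the same deleted operons, had signals of 436.2 and 317.8 in the wild type and 650.8 and 381.8 in the deletion array. The araD probe set thus passed the signal filter, so passing it may not show a signal above background. How much of araD and rhaD the deletions removed was not checked. Of the 2427 genes that passed, 1040 were brighter than all of these deleted genes in both arrays.

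Genes of acid resistance had the largest differences in the higher direction. The glutamate decarboxylase gene gadA was 6.44-fold higher in the deletion array (signals of 897.2 and 5776), the glutamate and 4-aminobutyrate antiporter gene gadC was 6.28-fold higher, and the acid resistance membrane protein gene hdeD was 5.25-fold higher. The second decarboxylase gene, gadB, was 5.08-fold higher, although gadA and gadB are nearly identical in sequence and the split between them is uncertain. In the lower direction, the porin pseudogene nmpC was 6.77-fold lower, the outer membrane protein gene ompW 5.62-fold lower, and tnaC, the leader peptide gene of the tryptophanase operon, 5.16-fold lower. By the size rule, 167 of the 2427 genes that passed the signal filter were at least 2-fold higher in the deletion array (6.88%) and 114 were at least 2-fold lower (4.70%). The other 2146 genes lay within 2-fold, and 13 genes were at least 4-fold higher and 8 at least 4-fold lower. The balance of the 2 directions depended on scaling. Genes in the higher direction made up 59.4% of the differing genes as deposited, 45.6% after quantile normalization (115 higher and 137 lower), 38.0% after a lowess on mean signal (90 and 147) and 11.9% when the arrays were scaled on added control transcripts (62 and 459). Under all of these scalings, median centring and a pseudocount, 40 genes stayed at least 2-fold higher and 51 at least 2-fold lower.

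Further genes among the 12 with the largest ratios in each direction had varied functions. The gene mcbA (ybiM), a member of the same protein family as ycfR, was 5.55-fold higher in the deletion array. The sodium-proton antiporter gene nhaA was 4.74-fold higher, the envelope protein gene osmY 4.12-fold higher, and the little-studied genes yohC, ybaA, ybgS, yceK and yjbJ between 4.14-fold and 5.43-fold higher. After the lowess, 11 of these 12 genes remained at least 2-fold higher, and yjbJ had a log2 ratio of 0.95. The proline utilization genes putA and putP were 4.74-fold and 3.77-fold lower, the galactitol transport genes gatC and gatB 4.48-fold and 4.06-fold lower, and the serine transporter gene sdaC 4.10-fold lower. The genes grcA (a spare part for pyruvate formate-lyase), feoA (iron(II) transport), atpB (ATP synthase) and rbsC (ribose transport) were 4.38-fold, 3.72-fold, 3.62-fold and 3.60-fold lower. All 12 of the genes with the largest ratios in the lower direction stayed at least 2-fold lower under each of the 5 other scalings and pseudocounts. Genes that were measurable in 1 array only have bounds. The 2-methylisocitrate lyase gene prpB was at least 4.26-fold higher, aidB at least 2.45-fold higher and phnN at least 1.92-fold higher. The galactitol dehydrogenase gene gatD was at least 4.38-fold lower, the tryptophanase gene tnaA at least 3.70-fold lower and ucpA at least 3.33-fold lower.

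As deposited, acid resistance and general stress genes had the highest medians among the gene lists. Of 12 acid resistance genes that passed the filter, 9 were at least 2-fold higher in the deletion array and none was lower. Besides gadA, gadB, gadC and hdeD, these included the periplasmic chaperone genes hdeA and hdeB (log2 ratios of 1.84 and 1.97), the regulator gene gadE (1.96) and slp (2.03). The regulator genes gadX and gadW had log2 ratios of 0.93 and 0.69. The list's median log2 ratio was 1.90, above each of 10000 random lists of equally bright genes, and it was 1.12 after the lowess, where 8 of the 12 remained at least 2-fold higher and hdeA was at 0.77. Of 29 general stress genes, whose transcription depends on the sigma factor RpoS, 17 were at least 2-fold higher and none was at least 2-fold lower. Among them were osmY (2.04), the lipoprotein gene osmB (1.79), the periplasmic superoxide dismutase gene sodC (1.72), ygaM (1.71) and dps, which encodes a DNA-binding protein of starved cells (1.53). Another 4 of the 29 had a lower signal in the deletion array, the lowest at -0.69. With the arrays scaled on added control transcripts, 8 of the 29 were at least 2-fold higher and 3 at least 2-fold lower. As deposited, the list's median was 1.07, at percentile 99.98 of the random lists. Many of these genes are bright. After the lowess osmY and sodC remained at least 2-fold higher at 1.12 and 1.17, while ygaM was at 0.99, osmB at 0.75 and dps at 0.19. Under that scaling 6 of the 29 remained at least 2-fold higher and the median was 0.49, at percentile 99.94, below the medians of glycolysis, type 1 fimbriae and the YhcN family under that scaling.

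Genes of sugar breakdown were higher as a group. Of 20 genes of glycolysis and glucose uptake, 6 were at least 2-fold higher in the deletion array and none at least 2-fold lower. They included the pyruvate kinase gene pykF (log2 ratio of 1.82), the enolase gene eno (1.504), the phosphoglucose isomerase gene pgi (1.46) and the glucose uptake gene crr (1.42). The list's median was 0.79, at percentile 99.64. It was 0.50 after the lowess, where 3 of the 20 remained at least 2-fold higher and eno and crr had values of 0.73 and 0.67. With the arrays scaled on added control transcripts, a uniform shift, the median was 0.29.

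Another 6 lists had medians above the 95th percentile, but their direction rests on the scaling of the arrays. Scaling on added control transcripts shifts each gene alike by -0.49, so that these 6 medians, all between 0 and 0.49, turn below 0 by construction while a list's place relative to equally bright genes is not affected beyond the random draws. Heat shock genes had a median of 0.48 (percentile 95.91) and -0.01 under that scaling. As deposited, 4 of 21 were at least 2-fold higher, among them hspQ (1.85), the chaperone gene dnaK (1.54), the protease gene hslV (1.13) and dnaJ (1.02). After the lowess hspQ alone of these remained at least 2-fold higher. Relatives of ycfR in the YhcN protein family had a median of 0.47 (percentile 95.11) and -0.03 under that scaling. They ranged from mcbA at 2.47 and yahO at 1.27, or 0.82 after the lowess, down to yjfN at -0.50. Type 1 fimbriae, which attach cells to surfaces, had a median of 0.43 (percentile 99.61) and -0.06 under that scaling, with 0 of 4 measurable genes at 2-fold and fimH at 0.55. Of these 4, only fimH (489.5 and 716.9) was brighter in both arrays than araD, which is counted as deleted (436.2 and 650.8). With a log2 ratio of 0.58, araD itself showed a difference of that size, so the fimbriae were not told apart from background. Oxidative stress genes had a median of 0.21 (percentile 96.03) and -0.28 under that scaling. Their members went both ways, with soxS and the superoxide dismutase gene sodA both at 1.41 and the multidrug resistance regulators marA and marR at -1.42 and -1.23, and sodA was at 0.62 after the lowess. Genes for the matrix polysaccharides poly-N-acetylglucosamine and cellulose had a median of 0.21 (percentile 96.35) and -0.28 under that scaling, and those for colanic acid 0.07 (percentile 95.30) and -0.42. None of the 2 and 6 measurable genes of these last lists reached 2-fold. After the lowess 3 of these lists no longer stood apart, with percentiles of 94.52 for oxidative stress, 93.72 for poly-N-acetylglucosamine and cellulose and 94.24 for colanic acid, and the YhcN family no longer did with the 75th percentile filter (87.2).

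**Figure D2:**
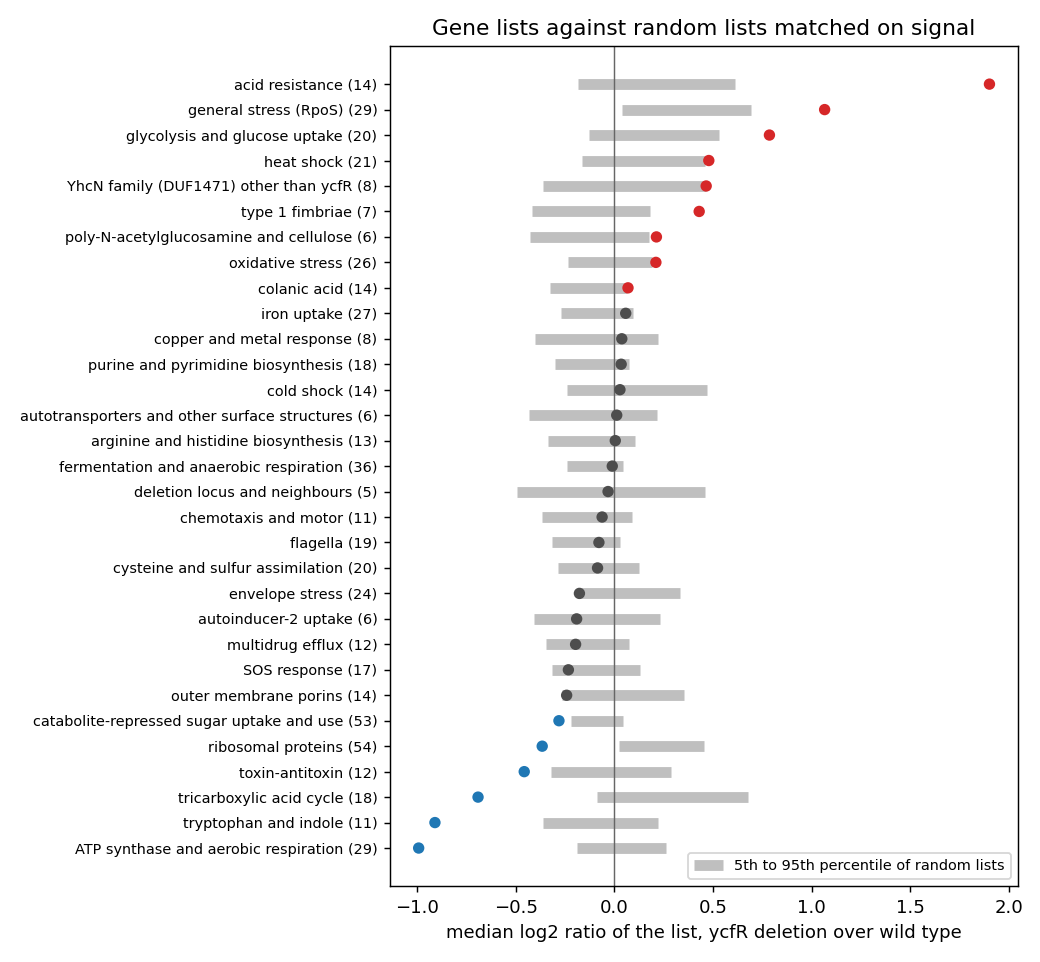
Each row is a gene list, with the log2 ratio of ycfR deletion over wild type on the horizontal axis and the list's median set against the 5th to 95th percentile range of random lists of equally bright genes. Acid resistance genes lie highest with a median of 1.90, and genes of ATP synthase and aerobic respiration lie lowest with a median of -0.99.

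Respiratory genes were lower in the deletion array. All 28 measurable genes of ATP synthase and aerobic respiration had a lower signal there, and 13 were at least 2-fold lower. Of 8 ATP synthase genes 7 were at least 2-fold lower, with log2 ratios of -1.86 for atpB, -1.76 for atpH, -1.74 for atpA and -1.67 for atpF. All 13 measurable genes of NADH dehydrogenase (nuo) were lower, with a median of -0.91, as were 5 cytochrome bo oxidase genes (cyo) with a median of -0.99, although cyoE at -0.098 turned just above 0 after quantile normalization and after the lowess. The list's median was -0.99, below each of the random lists. Of 17 genes of the tricarboxylic acid cycle, 4 were at least 2-fold lower and none was at least 2-fold higher. These were the succinyl-CoA synthetase gene sucD (-1.54), the 2-oxoglutarate dehydrogenase genes sucA (-1.23) and sucB (-1.22) and the succinate dehydrogenase gene sdhA (-1.08). After quantile normalization, the lowess and scaling on control transcripts, 7, 9 and 10 of the 17 were at least 2-fold lower. As deposited 4 genes were higher, namely aceB (0.84) and aceA (0.70) of the glyoxylate bypass, acnA (0.58) and gltA (0.29), and of these aceB, aceA and gltA turned below 0 after the lowess. The list's median was -0.69, also below each of the random lists.

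Genes of protein synthesis were lower by a small amount in the deletion array. Of 52 measurable ribosomal protein genes 41 had a lower signal there and none reached 2-fold in either direction. The largest differences were in rplQ (-0.995, just short of 2-fold), rpsJ (-0.96), rplT (-0.86) and rplD (-0.85). The median was -0.37, below each of the random lists, and it was -0.70 after the lowess, where 17 of the 52 were at least 2-fold lower. Of 10 measurable genes of tryptophan and indole metabolism, 3 were at least 2-fold lower, namely tnaC (-2.37) and the tryptophan operon genes trpL (-1.13) and trpC (-1.08), and trpE stood at -0.98. That list's median was -0.91, at percentile 0.005. Of 11 measurable toxin-antitoxin genes 1, the antitoxin gene mazE (-1.15), was at least 2-fold lower, and yafQ, yefM and mazF had log2 ratios of -0.78, -0.70 and -0.61. The median of that list was -0.46, at percentile 0.87, but it no longer stood apart with the 75th percentile filter (percentile 7.86).

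Genes for the use of sugars other than glucose, which glucose is known to repress, were lower for a part of the list. Of 41 measurable genes 10 were at least 2-fold lower and none was at least 2-fold higher. The ribose genes rbsD and rbsC had log2 ratios of -1.83 and -1.85, and the galactitol genes gatC and gatB of -2.16 and -2.02. The galactitol operon was not uniform, because gatY had a log2 ratio of 0.84 as deposited, which turned to -0.16 after the lowess. Among 8 measurable genes named mal, of which malI and malX are outside this list, the median was 0.38. Of these, 5 were higher and 3 lower, the lowest at -1.05. The median is smaller in size than the uniform shift of -0.49 that scaling on added control transcripts brings. The median of the whole list was -0.28, at percentile 0.585.

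As deposited, flagella, chemotaxis, porins and autotransporters lay within the range of random lists, unlike type 1 fimbriae and the matrix polysaccharides described above. Flagellar genes had a median of -0.08 and chemotaxis genes of -0.06. Of 39 flagellar genes 11 passed the filter, and 0 of these reached 2-fold. The master regulator genes flhD and flhC stood at -0.29 and -0.27, with deletion signals of 387.4 and 380.9. Of the curli genes, csgA alone passed the filter, with signals of 362.0 and 416.8. In the deletion array flhD, flhC and csgA were dimmer than araD, which is counted as deleted (650.8). Intergenic probe sets had medians of 280.0 and 264.5. Ratios near 0 at such signals do not show that these transcripts were present and unchanged. Outer membrane porins had members in both directions, with ompX at 1.93, nmpC at -2.76 and ompW at -2.49, and their median was -0.24, which stood apart with the 75th percentile filter (percentile 1.79). Iron uptake genes had a median of 0.06, while feoA was at -1.90 and the enterobactin genes entH and entB at -1.56 and -1.44. Envelope stress genes had a median of -0.18 that lay within the range as deposited but below it after quantile normalization, after the lowess and with 20 bins (percentiles 1.77, 1.39 and 4.18), with the phage shock genes pspA and pspC at -1.17 and -1.05 and osmB, also a general stress gene, at 1.79, or 0.75 after the lowess. Cold shock genes had a median of 0.03, which turned to -0.36 at percentile 3.34 after the lowess. Among them cspE was at 1.10 as deposited but at 0.03 after the lowess, and cspG and cspA were at -1.05 and -0.83. The gene cspB, with signals of 765.4 in the wild type and 133.4 in the deletion array, was lower but has a bound only. Fermentation and anaerobic respiration genes had a median of -0.01, with the alcohol dehydrogenase gene adhE at 1.04, or 0.71 after the lowess, and the hydrogenase genes hybA and hybO at -1.05 and -1.02, or -0.95 and -0.91 after it.

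The remaining lists also lay within that range as deposited. Autoinducer-2 uptake and synthesis genes had a median of -0.19, with the synthase gene luxS at 0.92 and lsrB at -0.63. The DNA damage (SOS) list had a median of -0.23, with uvrA at 0.95 and ruvA at -0.88. Purine and pyrimidine synthesis genes had a median of 0.03, with the CTP synthase gene pyrG at 1.72 as deposited and 0.98 after the lowess, where the list's median of 0.18 lay at percentile 95.59. Genes of copper and metal response had a median of 0.04, with the manganese uptake gene mntH at 1.76 and the zinc uptake gene znuA at -1.08, which was just short of 2-fold after the lowess. Medians were -0.08 for cysteine and sulfur assimilation, 0.01 for arginine and histidine synthesis, -0.20 for multidrug efflux, 0.01 for autotransporters (outside the range without a filter, at percentile 98.04) and -0.03 for the deletion locus with its neighbours. Of the 31 lists with a percentile, 9 lay above the 95th and 6 below the 5th, where the rule alone would place 3.1 outside. The lists share genes and operons, so they are not independent. Random lists were drawn gene by gene, whereas genes of the same operon within a list tend to move together. The percentiles and the 3.1 take no account of that, so lists made of few operons can look more extreme than they are.

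Closely spaced neighbouring genes, many of which share a transcript in bacteria, gave a check of single-gene ratios within this unreplicated pair. Strand was not known, so some pairs may lie on opposite strands. Across 627 pairs of adjacent measurable genes separated by fewer than 50 bases, the log2 ratios had a Pearson correlation of 0.70 and a Spearman correlation of 0.69. Random pairings of equally bright genes gave a mean of 0.02 and a highest value of 0.17 in 10000 draws. When the first gene of such a pair differed by at least 2-fold, the second had the same direction in 50 of 55 pairs (90.9%). For the 834 pairs farther apart the Pearson correlation was 0.33, and 83 of 114 pairs (72.8%) shared a direction. This check covers noise between probe sets and says nothing of the variation between cultures.

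**Figure D3:**
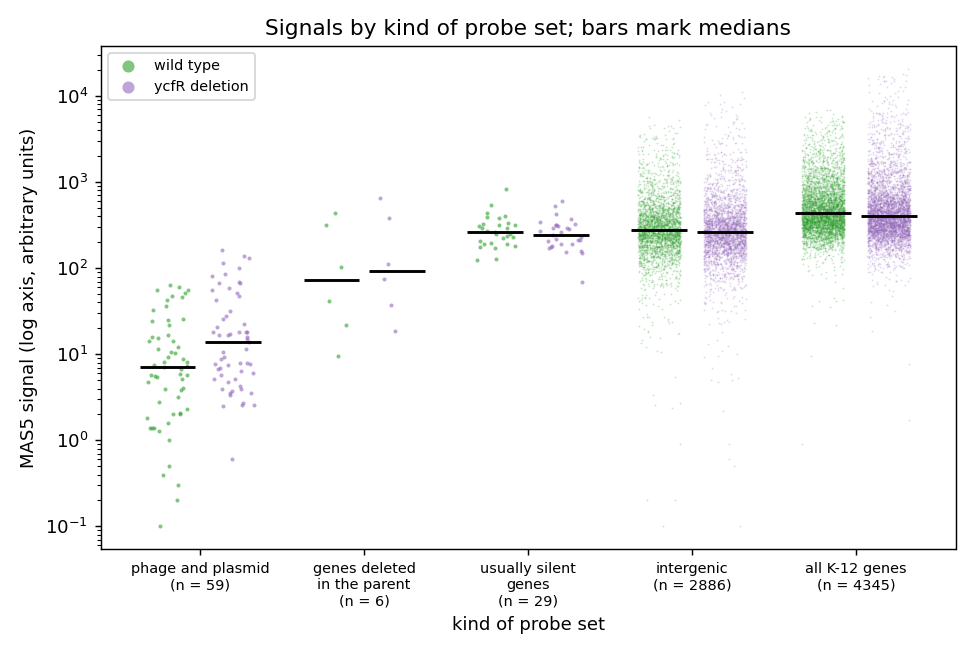
Signals of several kinds of probe set are drawn for the wild-type and the ycfR deletion array on a log axis in arbitrary intensity units. Phage and plasmid probe sets have medians of 7.1 and 13.7, the 6 genes deleted in the parent strain have medians of 72.7 and 93.4, and intergenic probe sets have medians of 280.0 and 264.5.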

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

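Every test in this part was chosen after the list values were seen, except those on ribosome hibernation genes and on Crp-activated genes, which were fixed before the values of those genes were looked at. Signals of probe sets that stand for no K-12 gene were examined on their own. Phage and plasmid probe sets, many of them for phage lambda and the F plasmid, had a median log2 ratio of 1.15, with 49 of 59 brighter in the deletion array at medians of 7.1 and 13.7. The added bacterial control transcripts (Dap, Lys, Phe and Thr) had a median log2 ratio of 0.49, and 12 of 12 probe sets were brighter in the deletion array. The manufacturer controls BioB-5 (659.4 and 715.3) and BioC-3 (332.3 and 255.7), outside that set, had log2 ratios of 0.12 and -0.38. The shift was thus not shared by all bright controls, and why was not tested. The remaining manufacturer controls had signals of 25.8 or less. Among 790 intergenic probe sets that passed the filter, 47 were at least 2-fold higher and 29 at least 2-fold lower in the deletion array.

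Acid resistance and general stress genes were higher in the deletion array, with list medians of 1.90 and 1.07. A difference between the arrays that grows with brightness is argued against as the whole cause for the acid list, which kept a median of 1.12 after a lowess. The general stress list, as deposited, lay at percentile 99.98 of equally bright genes. It was taken up because it stood apart in this way, so that percentile is no separate test. Much of the size of the general stress difference went with brightness, since the lowess took its median to 0.49 and its 2-fold members from 17 to 6. Stronger labelling or scaling of the whole deletion array is argued against for the acid list, whose median less that of the control transcripts was 1.41. The general stress median exceeded the 95th percentile of equally bright lists by 0.37. A shift common to all genes cannot give that, but it restates why the list was taken up and is no separate test. A deletion culture further into stationary phase may account for the pattern and stays open: the ribosome hibernation genes rmf, raiA, ettA, sra and hpf reached a median of 1.03, as that explanation predicted, but at percentile 88.74 they did not stand apart from equally bright genes. With 1 culture per genotype, the loss of ycfR cannot be told apart from the age or the acidity of the culture.

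Genes of ATP synthase, respiration, the tricarboxylic acid cycle and ribosomal proteins were lower in the deletion array. Ribosomal RNA taking signal from all other transcripts alike would lower every list by the same amount. The medians of respiration and the tricarboxylic acid cycle lay at -0.95 and -0.65 relative to the median of all measurable genes. A shift common to all genes cannot give that. But these lists were taken up because they stood apart from other genes, so it is no separate test. The median of ribosomal proteins lay at -0.39 relative to the 5th percentile of equally bright lists. That restates why the list stood apart and is no separate test. The trend with brightness ran upward in the deletion array. Random lists as bright as respiration, the cycle and ribosomal proteins had medians of 0.03, 0.28 and 0.24. A trend in that direction does not account for lower values. After the lowess the list medians were -1.11, -0.95 and -0.70, each farther below 0 than as deposited. Removing an upward trend sets lists of bright genes lower by construction, so the lowess was no separate test. Lower activity of Crp, the regulator of catabolite repression, may contribute and stays open: Crp-activated genes outside sugar use lay at percentile 6.38, close to but not past the limit of 5, with cstA at -1.21 and dctA at -1.25 but udp at 0.35. A difference between genotypes stays among the open explanations, as untested.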

How the results depend on the processing

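Of the 15 lists that stood apart, 10 kept their side of the percentile limits in every alternative run on them: acid resistance, general stress, glycolysis, heat shock, type 1 fimbriae, respiration, the tricarboxylic acid cycle, ribosomal proteins, tryptophan, and sugar use. Type 1 fimbriae had too few bright members for the 75th percentile filter, so that alternative was not run on them. The ycfR log2 ratio ranged from -6.88 to -1.75 and the correlation of close neighbours from 0.58 to 0.79. Scaling on added control transcripts, chosen after seeing the data, reversed the medians of YhcN relatives (-0.026), type 1 fimbriae (-0.061), colanic acid (-0.42), poly-N-acetylglucosamine and cellulose (-0.28), heat shock (-0.013) and oxidative stress (-0.28), by construction of its uniform shift of -0.49, which tests no list against other genes. Without a filter colanic acid (-0.054) and poly-N-acetylglucosamine and cellulose (-0.057) were reversed, as was colanic acid with a pseudocount (-0.037). Medians that no longer stood apart were 0.24 (pseudocount), 0.47 (no filter, and 20 bins) and 0.62 (75th percentile) for YhcN relatives; 0.19 (quantile, and lowess) and 0.070 (no matching) for colanic acid; 0.30 (quantile), 0.28 (lowess) and 0.21 (no matching) for poly-N-acetylglucosamine and cellulose; 0.17 (lowess), 0.068 (pseudocount) and 0.33 (75th percentile) for oxidative stress; and -0.41 (75th percentile) for toxin-antitoxin genes. The cause was not tested. Among lists within the limits, 7 of the alternative values lay outside them: envelope stress (quantile, lowess and 20 bins), cold shock and purine and pyrimidine synthesis (lowess), porins (75th percentile) and autotransporters (no filter).

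The count of 167 higher genes became 90 with the lowess, 62 with control transcript scaling, 382 at 1.5-fold, 45 at 3-fold and 387 after subtracting a floor. The count of 114 lower genes became 51 with a pseudocount, 459 with control transcript scaling and 369 at 1.5-fold. It became 23 at 3-fold, 287 after subtracting a floor and 28 among the 1040 genes above the deleted genes. The other 13 counts lay within 1.5 times the reported ones. The floor subtraction and the count without shared probe sets, ribosomal and transfer RNA (141 and 104) were also chosen after seeing the data. Of 660 alternative log2 ratios of named genes, 56 lost and 27 gained the 2-fold size and none of the at least 2-fold ratios changed sign. No paired analysis was possible because each group had 1 array, and for the same reason no array could be left out. The planned choice of the brightest probe set was not run, since each gene had 1. How far dim genes lie above background was not tested gene by gene. In the wild type 99.7% of K-12 genes exceeded the brightest phage or plasmid probe set, and in the deletion array 95.8% did. The genes araD and rhaD, counted here as deleted, exceeded it too, so this does not by itself show transcription. The median signals of K-12 genes were 435.1 and 399.4 against 280.0 and 264.5 for intergenic probe sets, which also stand for the chromosome.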

Other observations

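The groups and genes in this part were chosen after their values were seen, and the test on DNA carry-over was chosen after its pattern was seen. The nucleoside breakdown genes deoA, deoB, deoC and deoD were higher in the deletion array, with log2 ratios of 1.78, 1.476, 1.79 and 1.604, while the gene of their repressor, deoR, was at -0.23. After the lowess deoB was at 0.86 and the other 3 remained at least 2-fold higher. Of the 5 genes of iron-sulfur cluster assembly named isc, 4 were at least 2-fold higher, with iscU at 1.59, iscS at 1.498, iscR at 1.46 and iscA at 1.39, and iscX was at 0.33. After the lowess iscA was at 0.84. The peptide uptake operons were lower. All 5 oligopeptide genes (opp) had lower signals, with a median of -1.10 and oppC at -1.42, and all 5 dipeptide genes (dpp) did, with a median of -1.28 and dppD at -1.73.

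Ribosomal RNA probe sets were among the brightest on both arrays, and they are shared between gene copies. All 18 were at least 2-fold higher in the deletion array as deposited, with a median log2 ratio of 1.496. After the lowess the median was 0.20 and 0 of 18 reached 2-fold. These probe sets lie at the bright end and entered the lowess fit themselves, so this does not show that brightness was the cause. The wild-type signals of these probe sets ran from 3324 to 6937 and the deletion signals from 11237 to 20709.

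K-12 genes that are usually silent in culture, such as those of cryptic fimbriae, had signals above most genes that the strain lacks. The hypothesis was carry-over of genomic DNA into the labelled sample, which would lift each sequence present in the chromosome. The median of 29 such genes was 8.24 times that of araA, araB, rhaA and rhaB in the wild type (261.2 over 31.7) and 4.33 times in the deletion array (243.6 over 56.2), and intergenic probe sets had medians 8.83 and 4.70 times those of the 4 genes. With araD and rhaD included, whose signals exceeded the silent median although their operons are deleted, the ratios were 3.60 and 2.61 for silent genes and 3.85 and 2.83 for intergenic probe sets, the last below the 3 times that the hypothesis required. Forward and reverse intergenic probe sets had similar medians, 272.3 and 289.2 in the wild type and 263.7 and 264.7 in the deletion array. DNA carry-over may contribute but stays open, because the outcome depends on whether araD and rhaD are counted. How much of these genes the deletions removed was not checked, and low transcription across the chromosome was not tested. After a floor was subtracted, 387 genes were at least 2-fold higher and 287 at least 2-fold lower, so a common floor would make the reported ratios too small.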
